A study of synthetic RNA with 26 samples.

How the data were processed

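The 26 libraries come from a massively parallel dicing assay, in which the ribonuclease DICER cleaves a pool of synthetic pre-mir-324 hairpins that differ at a few bases and the RNA is then sequenced. 2 control libraries sample the pooled substrates before cleavage, and 24 libraries sample cleavage products. The products come from 2 enzymes, labelled hDICER and fDICER, and from 4 substrate subgroups, labelled A, T, G and C, with 3 libraries for each of the 8 combinations. The sources used here do not define the labels hDICER and fDICER, and they do not say whether the 3 replicates of a group are separate cleavage reactions, so the p-values measure spread between libraries, which can be technical. Per the labels, the control libraries were made by circular ligation, whereas the product libraries received adapters at both ends and were made separately for each subgroup. The adapters are named 4N, and whether random bases in them were used to remove duplicate reads is not given in the sources used here.

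The deposited files of the authors hold raw counts of reads per sequence, with no normalization. The processing notes name cutadapt and BWA without version or role. Each substrate has 56 nt: a variable base at nt 1, which defines the subgroup (U in subgroup T), a fixed core of 52 nt at nt 2 to 53, and 3 variable bases at nt 54 to 56, called the triplet here. Together these give 256 substrates, 64 triplets in each of 4 subgroups. Product molecules are 3′ fragments that end with the triplet and do not contain nt 1, so the subgroup of a product is known only from its library. The unmutated sequence is not marked in the files and is not singled out here. Files of the 2 enzymes differ in layout and in length limits: hDICER files hold fragments of 15 to 56 nt, and fDICER files hold fragments of 4 to 55 nt. Products of at least 15 nt were used throughout. Any other difference in how the files of the 2 enzymes were made cannot be told apart from the enzyme, and any difference between the preparations of the 4 subgroups cannot be told apart from the subgroup.

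A product feature is a triplet with a product length, written as CUA_20 for the 20-nt product of triplet CUA. The share of a cleavage site is the percentage of a library's counts of at least 15 nt that have 1 product length, and 11 lengths from 15 to 25 nt were tested. Counts per library were 312071 to 848278 for hDICER and 84632 to 1001799 for fDICER at 15 nt and over. At these depths the 95% Wilson interval of the 22-nt share of a single library extends 0.0947 to 0.332 points to each side. These intervals cover counting error only, since reads are not independent molecules where duplicates were not removed.

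Changed features were found with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood tests, TMM normalization, features with at least 10 counts in at least 3 libraries, Benjamini-Hochberg adjusted p under 0.05, two-sided). Comparisons were hDICER against fDICER in each subgroup, the interaction of enzyme and subgroup over all 24 product libraries, and the difference between the 4 subgroups within each enzyme. For products against control, counts were summed over product lengths for each triplet, compared with the 56-nt sequences of the same substrates in the 2 control libraries, and filtered at 10 counts in both of these. Because TMM sets the typical substrate of a comparison to no change, these results are relative to the other triplets of the subgroup. Log2 ratios of product share to control share were also computed with a pseudocount of 0.5 counts, and a base was contrasted with the other bases at its position.

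Site shares of the 2 enzymes were compared by exact two-sided permutation of the enzyme labels within subgroups (160000 arrangements, smallest p 1.25e-05) and within each subgroup (3 against 3 libraries, 10% of random arrangements separate the groups completely, smallest p 0.1). Subgroups were compared by an exact permutation test of the F statistic over all 369600 partitions of 12 libraries (smallest p 6.49e-05), in place of the 100000 resamples first chosen. The interaction of enzyme and subgroup in a site share was tested with 100000 Freedman-Lane permutations of residuals. Base effects were tested with exact sign flips over 12 libraries (4096 flips, smallest p 0.000488). The flips treat the libraries as independent, although 3 come from each of 4 subgroups and may be technical repeats. Their p and the SD over 12 libraries can therefore overstate the evidence for a base effect that holds across subgroups. All 12 product libraries of an enzyme share the 2 control libraries, so the sign-flip p of a product to control ratio covers only the spread between product libraries. Feature classes were the base at each of the 3 triplet positions, the number of G or C in the triplet, the product length, and whether nt 1 and nt 54 can form a Watson-Crick pair, a G-U pair or a mismatch. Within a subgroup the Watson-Crick class is 1 base at nt 54, and so is the G-U class in T and G. In A and C, which have no G-U class, mismatches are all other triplets. Classes therefore overlap, and counts of classes called are not counts of separate results. Classes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Minimum free energy structures of the 256 substrates were computed with RNAfold 2.7.2. Other calculations used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

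The comparisons, tests, classes, naming rule and most alternatives were fixed before the data were examined. Features are named by this rule: in each enzyme comparison up to 5 with the highest and 5 with the lowest log2 fold change, among those with adjusted p under 0.05, an average of at least 50 counts and completely separate libraries; up to 3 each way for products against control and up to 6 for subgroup differences; every site with at least 5% of the counts in a group; and the 3 features with most counts in each group. The alternatives were DESeq2 size factors, library totals, other count minimums, the DESeq2 1.42.0 test, the replicate number as a block, leaving out each library, 1 fit over 24 libraries, control counts limited to the subgroup, a mean share over triplets with at least 20, 50 or 200 counts, a pseudocount of 5, camera on features with at least 100 counts on average, and camera with an estimated correlation. Chosen after seeing the data were all product lengths, 20 to 22 nt only, leaving out the 4 fDICER libraries numbered 1, leaving out the shallowest fDICER library, a control that includes 57-nt and 58-nt sequences, and subgroup labels permuted within library numbers. Replicate numbers are not treated as pairs, since nothing in the labels links equal numbers.

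The procedures were tested on simulated data with the depth and spread of each comparison. At a 4-fold change, edgeR recovered 94.6% of changed features in subgroup A, 100% in T, 98.9% in G and 85.1% in C for the enzyme comparison, 65.7% for the interaction, 99.0% for the hDICER subgroup difference and 58.2% for the fDICER subgroup difference. At a 2-fold change the fDICER subgroup difference recovered 4.08%. Left out of the comparisons were fragments under 15 nt, which only the fDICER files hold, and the 57-nt and 58-nt sequences of control library 1. Control libraries hold whole substrates of 56 to 58 nt, so they give no background for the product lengths.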

Results

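The data are counts of sequenced RNA from 26 libraries: 2 controls of uncleaved pre-mir-324 substrates and 3 product libraries for each of 2 enzymes and 4 substrate subgroups. Control library 1 held 2676752 counts and control library 2 held 1467764. Total counts ran from 312071 to 848278 in the 12 hDICER libraries and from 85497 to 1011221 in the 12 fDICER libraries, where the lowest total was that of fDICER C library 3. All 64 triplets were found in each of the 24 product libraries. DICER measures a hairpin from its end and cleaves at a distance from it, so the length of the 3′ fragment shows which site was used. Products of 20, 21 and 22 nt made up 94.3% to 96.0% of the counts in hDICER libraries and 93.0% to 97.1% in fDICER libraries. The 22-nt product CCACUGCCCCAGGUGCUGCNNN starts at nt 35, the 21-nt product CACUGCCCCAGGUGCUGCNNN at nt 36 and the 20-nt product ACUGCCCCAGGUGCUGCNNN at nt 37, where NNN is the triplet. The most abundant single features had A at nt 54 in all 8 groups, such as ACA_21 with 3.22% ± 0.374 (SD, n = 3) of the hDICER subgroup G counts and ACU_22 with 3.01% ± 0.126 (SD, n = 3) of the fDICER subgroup T counts. This follows the substrate pool: in the ratio of product to control, A at nt 54 did not exceed the other bases (mean log2 -0.03 with hDICER and -0.24 with fDICER).

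The first question is whether the base at nt 1 goes with the site that hDICER uses. With U at nt 1 (subgroup T) the 22-nt product dominated, at 64.7% ± 0.942 (SD, n = 3) of the counts, whereas with G at nt 1 it made up 32.2% ± 1.78. There the 21-nt product took the largest share. The 21-nt share was 54.7% ± 2.02 in subgroup G, 37.8% ± 1.04 in A, 29.1% ± 0.915 in C and 19.9% ± 0.588 in T (SD, n = 3 each). Subgroups A and C had 22-nt shares of 49.8% ± 1.32 and 54.9% ± 0.567. The 20-nt share was highest in subgroup C at 11.1% ± 1.18 and lowest in A at 7.83% ± 0.526, with 9.85% ± 0.770 in T and 8.16% ± 0.488 in G. All 3 differences passed. The 22-nt range of 32.6 points and the 21-nt range of 34.8 points each had an exact permutation p = 6.49e-05, the smallest possible, and an adjusted p = 0.000357 over 11 lengths. The 20-nt range of 3.23 points had an exact permutation p = 0.00682 and adjusted p = 0.0188. Every library of 1 subgroup lay apart from every library of another in all 6 pairs of subgroups for the 21-nt and the 22-nt share, which chance gives in 10% of pairs. Of the rarer products, the 23-nt share also differed, from 0.755% in subgroup G to 1.38% in T (adjusted exact permutation p = 0.00643), as did the 24-nt share, from 0.132% to 0.267% (adjusted p = 0.0193). In control library 1, 77.8% of the 56-nt and 57-nt sequences with G next to the core had 57 nt, against 19.3% with A, 20.1% with U and 35.6% with C, and control library 2 holds 56-nt sequences alone.

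With fDICER, subgroup T again had the largest mean 22-nt share, 74.5% ± 0.268 (SD, n = 3), and subgroup G the smallest, 51.5% ± 6.65, but the differences did not pass the correction over 11 lengths when labels were permuted over all 12 libraries. Subgroup A had 60.1% ± 4.52 and subgroup C 54.7% ± 13.8. The 22-nt range of 23.03 points had an exact permutation p = 0.0404 and the 21-nt range of 21.96 points p = 0.0468, each with adjusted p = 0.129. The 20-nt range of 3.21 points had an exact permutation p = 0.0225 and adjusted p = 0.124. Libraries of 1 subgroup differed widely in A, G and C and little in T. In subgroup C the 22-nt share was 69.3% in library 1, 52.8% in library 2 and 41.9% in library 3, and in subgroup G it was 59.1%, 48.5% and 46.8%. Subgroup A had 64.1%, 61.0% and 55.2% and subgroup T 74.7%, 74.2% and 74.5%, so T lay above A and A above G within each library number. Without fDICER C library 1 all 3 ranges passed, at 27.1 points (adjusted exact permutation p = 0.0236), 22.1 points (0.0345) and 4.42 points (0.0236) for 22, 21 and 20 nt. Without the 4 fDICER libraries numbered 1 the ranges were 27.02, 24.6 and 4.50 points, each with an adjusted exact permutation p = 0.105. Over all alternatives the adjusted p ran from 0.0236 to 0.292, from 0.0345 to 0.292 and from 0.0236 to 0.250. The 4 fDICER libraries numbered 1 also held 2.69% to 4.47% of their counts in fragments under 15 nt, against 0.556% to 1.23% in the other 8.

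**Figure D1:**
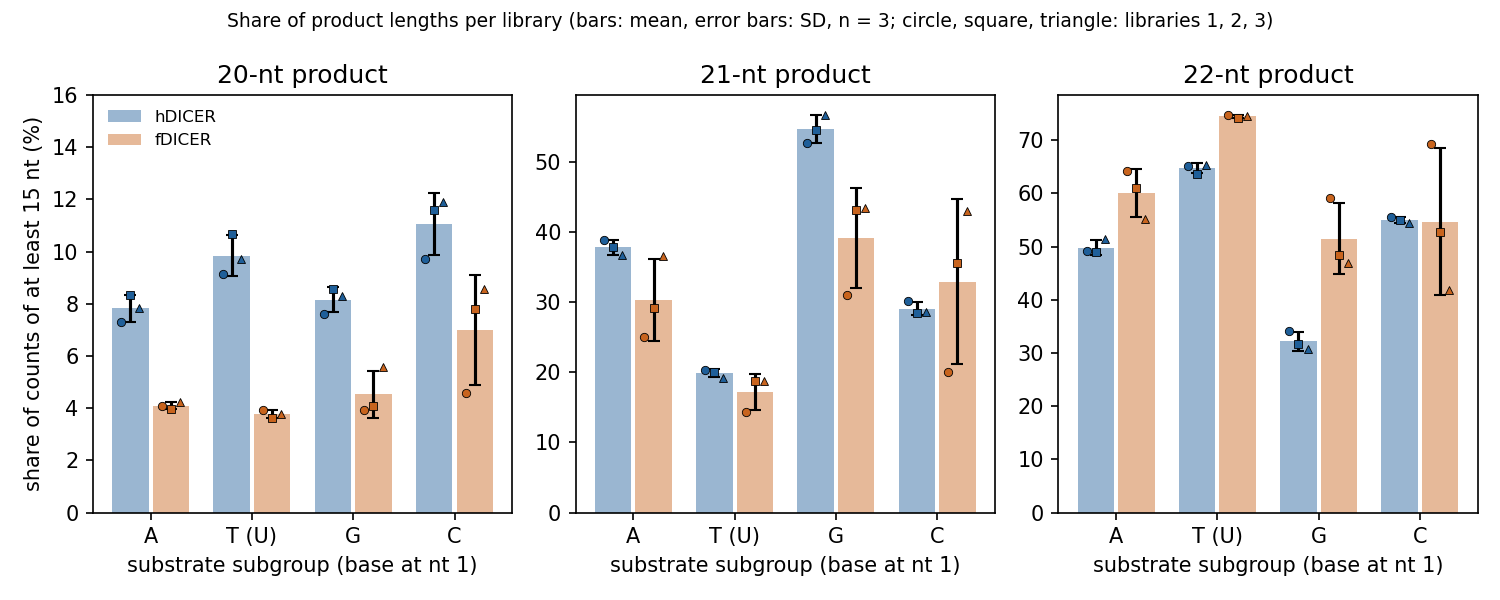
Share of the counts of at least 15 nt (percent) in the 20-nt, 21-nt and 22-nt products for each enzyme and substrate subgroup; points are libraries and bars are means of 3 libraries. hDICER libraries of 1 subgroup lie within 3.43 points of each other in the 22-nt share, and those of fDICER subgroup C spread from 41.9% to 69.3%.

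The second question is how the 2 enzymes differ on the same substrates. hDICER made more of the 20-nt product, 9.22% against 4.85% of the counts as means over the 4 subgroups, and less of the 22-nt product, 50.4% against 60.2%. The 20-nt share was higher with hDICER by 3.74 points in subgroup A, 6.07 in T, 3.62 in G and 4.07 in C, and every hDICER library lay above every fDICER library in each of the 4 subgroups. The 22-nt share differed by -10.3 points in A, -9.74 in T and -19.3 in G, with complete separation in these 3 subgroups, and by 0.252 points in C, where the libraries overlapped. The 21-nt share was higher by 7.51 points in A, 2.61 in T and 15.5 in G, again with complete separation, and differed by -3.85 points in C. The small 15-nt product was rarer with hDICER in all 4 subgroups, at 0.0618% against 0.203%; 15 nt is also the shortest length in the hDICER files. Complete separation arises by chance in 10% of arrangements of 3 against 3, and the exact permutation p was then 0.1, the smallest possible. In subgroup C the 22-nt difference had the other sign without hDICER C library 1 (-0.0336 points), fDICER C library 2 (-0.676 points) or fDICER C library 3 (-6.14 points), and the 21-nt difference was 1.22 points without fDICER C library 3.

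Over the 4 subgroups the 20-nt difference of 4.37 points and the 15-nt difference of -0.141 points each had an exact permutation p = 1.25e-05, the smallest possible, and an adjusted p = 6.88e-05. The 22-nt difference of -9.77 points had an exact permutation p = 0.00208 and adjusted p = 0.00761. The 21-nt difference of 5.44 points had an exact permutation p = 0.0484 and did not pass the correction (adjusted p = 0.107). Against fDICER library 1 alone, the hDICER mean differed in the 22-nt share by -14.3 points in A, -9.99 in T, -26.9 in G and -14.4 in C, and against fDICER libraries 2 and 3 by -8.30, -9.62, -15.5 and 7.58 points. The 20-nt difference was 3.74, 5.91, 4.23 and 6.48 points against library 1 and 3.73, 6.15, 3.32 and 2.86 points against libraries 2 and 3 in the same order. The 21-nt difference was 12.8, 5.58, 23.7 and 8.99 against 4.87, 1.13, 11.4 and -10.3 points. Without the 4 fDICER libraries numbered 1 the 22-nt difference over the subgroups was -6.46 points (adjusted exact permutation p = 0.0453, in a range over all alternatives from 0.000229 to 0.0453). Without the same 4 libraries the 21-nt difference was 1.77 points (adjusted exact permutation p = 0.599). Without fDICER C library 3 it was 6.70 points and passed (adjusted exact permutation p = 0.0142, in a range from 0.0142 to 0.599).

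Whether the enzymes differ by subgroup was tested directly. The interaction of enzyme and subgroup gave permutation p = 0.0390 for the 21-nt share, 0.0528 for the 22-nt share and 0.155 for the 20-nt share, and none passed the correction (adjusted p = 0.0793, 0.0793 and 0.155). Without the fDICER libraries numbered 1 all 3 passed, with adjusted permutation p = 0.00012, 0.00012 and 0.0191. Among single features edgeR called 0 of 653 for the interaction, with 43 at an unadjusted p under 0.05 and 21 called by DESeq2. It called 122 without the libraries numbered 1, 9 without fDICER T library 1 and 3 without fDICER C library 1.

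At the level of single features, 124 of 584 differed between the enzymes in subgroup A (60 higher and 64 lower with hDICER), 98 of 584 in T (52 higher and 46 lower) and 118 of 527 in G (49 higher and 69 lower). Among the features that met the naming rule, most of the largest increases with hDICER were in 20-nt products of triplets ending in UA. UUA_20 was 9.26-fold higher in subgroup A (log2 3.21 ± 0.37 SE, edgeR adjusted p = 0.00219), 6.63-fold in T (adjusted p = 0.000424) and 5.40-fold in G (adjusted p = 0.00979). GUA_20 was 6.52-fold, 5.09-fold and 4.57-fold higher in the same order. CUA_20 was higher by 5.34-fold in T and 6.09-fold in G, and AUA_20 4.18-fold in A and 4.47-fold in T. UCA_20 was 4.50-fold higher in A and 3.42-fold in T. Of longer products, UUA_21 was 5.24-fold higher in A, and GUA_21 and GUA_23 were 4.60-fold and 5.03-fold higher in G. Without fDICER G library 1, CUA_20 was 10.7-fold and GUA_23 10.9-fold higher in G. Under the same rule most of the largest decreases were in 22-nt products of triplets ending in G. Outside it the lowest log2 differences of 15-nt features were -2.98 in A, -2.99 in T and -2.86 in G. CCG_22 was 4.63-fold lower in A, 2.95-fold in T and 7.03-fold in G (log2 -2.81 ± 0.34 SE, edgeR adjusted p = 0.00311). CUG_22 was 3.52-fold lower in A and 6.36-fold in G, and also lower in T. CGG_22 was lower by 5.16-fold in A and 5.17-fold in G, GGG_22 3.25-fold in T and 5.72-fold in G, and UGG_22 5.63-fold in G. The other named features were lower as well: CCG_18 by 4.26-fold and CUU_15 by 4.18-fold in A, and GGC_22 by 2.99-fold and CUU_16 by 2.94-fold in T. These folds combine the amount of a triplet over all lengths with the site used. Summed over lengths, UUA in subgroup A was 7.54-fold below control with fDICER and 1.86-fold with hDICER. CGG in subgroup A was 5.43-fold above control with fDICER and 2.69-fold with hDICER.

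Grouped by length, 34 of 64 20-nt features were higher in subgroup A, 34 in T and 25 in G, and 0 were lower (40, 41 and 28 higher when adjusted over the list alone). Their median log2 differences were 0.88, 0.90 and 0.87, with camera adjusted p = 3.68e-23, 1.02e-23 and 2.62e-12; adjusted p = 0.382, 0.447 and 0.682 with an estimated correlation. 22-nt features were lower in 21, 15 and 35 of 64 and higher in 3, 2 and 0 (lower in 25, 33 and 42 and higher in 4, 2 and 1 when adjusted over the list alone). Their medians were -0.33, -0.68 and -0.97, with camera adjusted p = 0.00159, 1.90e-08 and 2.09e-14; adjusted p = 0.555, 0.579 and 0.0916 with an estimated correlation. Of the 21-nt features 12, 4 and 11 were higher and 1, 1 and 0 lower (12, 3 and 9 higher when adjusted over the list alone). By camera the adjusted p were 0.00867, 0.403 and 0.000917, and adjusted p = 0.778, 0.973 and 0.722 with an estimated correlation. In subgroup T their median of -0.30 had the opposite sign to the difference in the 21-nt share of the counts. 15-nt features were lower in 19 of 33, 11 of 17 and 17 of 27 (21, 17 and 24 when adjusted over the list alone), with medians of -1.69, -2.16 and -1.78. For these classes camera gave adjusted p = 3.66e-12, 1.78e-09 and 3.47e-12, and adjusted p = 0.382, 0.499 and 0.0916 with an estimated correlation. Other lengths passed in single subgroups: 16 nt downwards in T (camera adjusted p = 0.000131), 17 nt downwards in G (0.00643), 23 nt upwards in T and G (0.009997 and 0.00695) and 24 nt upwards in T and G (0.0493 and 0.0194). Their adjusted p = 0.581, 0.682, 0.754 and 0.682, and 0.804 and 0.722 with an estimated correlation. Changed were 9 of 57, 7 of 61, 5 of 63, 7 of 52, 1 of 53 and 0 of 24 features in that order by edgeR (9, 4, 2, 0, 0 and 0 when adjusted over the list alone). Features of 18, 19 and 25 nt did not pass in A, T or G.

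Grouped by base, features with A at nt 56 were higher in 33 of 154 in subgroup A, 29 of 147 in T and 26 of 135 in G and lower in 5, 4 and 7 (36, 36 and 27 higher when adjusted over the list alone). The camera adjusted p were 5.43e-09, 9.16e-09 and 2.18e-06, and with an estimated correlation adjusted p = 0.382, 0.447 and 0.682. Triplets with A at nt 56 held 29.7% ± 0.879 (SD, n = 3) of the hDICER and 21.9% ± 2.05 of the fDICER counts in subgroup A (exact permutation p = 0.1, the smallest possible). Features with G at nt 56 were lower in 27 of 141, 15 of 139 and 29 of 129 and higher in 5 each (27, 15 and 35 lower when adjusted over the list alone), with camera adjusted p = 4.84e-06, 0.00345 and 7.71e-05; adjusted p = 0.555, 0.579 and 0.682 with an estimated correlation. Features with A at nt 55 were higher in 19 of 139, 18 of 142 and 17 of 127 (17, 18 and 16 when adjusted over the list alone), and those with G at nt 55 were lower in 22 of 140, 12 of 138 and 24 of 125 (12, 1 and 24 when adjusted over the list alone). Camera adjusted p were 0.000363, 0.00973 and 0.00695 for A and 1.56e-05, 0.0196 and 2.40e-05 for G, and adjusted p = 0.555, 0.447 and 0.682 and 0.555, 0.593 and 0.682 with an estimated correlation. Triplets of 3 G or C were lower in 15 of 65, 11 of 64 and 11 of 54 and higher in 1, 1 and 3 (15, 12 and 13 lower when adjusted over the list alone). Triplets of A and U alone were higher in 20 of 78, 13 of 77 and 12 of 72 and lower in 3, 2 and 7 (21, 14 and 12 higher when adjusted over the list alone). Camera adjusted p were 1.70e-05, 0.000320 and 0.00884 for the former and 2.04e-07, 0.00659 and 0.00738 for the latter, and adjusted p = 0.561, 0.499 and 0.682 and 0.555, 0.593 and 0.722 with an estimated correlation. Triplets with 2 G or C passed downwards in all 3 subgroups (6.22e-05, 0.0163 and 0.0370; 33, 19 and 28 lower and 9, 8 and 11 higher), and those with 1 passed upwards in A and T (0.00173 and 0.009997; 30 and 30 higher and 13 and 14 lower), with adjusted p = 0.555, 0.447 and 0.682 and 0.555 and 0.499 with an estimated correlation. When adjusted over the list alone 27, 16 and 26, and 27 and 32, changed in these directions. C at nt 54 passed downwards in A and T (0.000124 and 0.0493; 29 and 21 lower, 32 and 21 when adjusted over the list alone) and U at nt 55 upwards in A and T (0.00677 and 0.0196; 30 and 24 higher, 35 and 28 when adjusted over the list alone). Passing in T and not in A or G were U at nt 54 upwards (0.0341; 16 higher and 4 lower, 9 higher when adjusted over the list alone), and downwards C at nt 55 (0.00973; 19 lower and 7 higher) and U at nt 56 (0.0261; 19 lower and 8 higher), with 19 and 19 lower when adjusted over the list alone. These 5 classes had adjusted p = 0.555 and 0.447, 0.555 and 0.499, 0.579, 0.499 and 0.499 with an estimated correlation. A and G at nt 54 and C at nt 56 did not pass in A, T or G. Classes by the pair of nt 1 and nt 54 did not pass in these 3 subgroups, with camera adjusted p = 0.269 in A, 0.557 in T and 0.283 in G for Watson-Crick pairs and 0.574 in T and 0.383 in G for G-U pairs. For mismatches it was 0.269, 0.9505 and 0.164 in A, T and G. Camera called 14 of 29 classes in A, 19 of 30 in T and 14 of 29 in G, and 0 of them with an estimated correlation (3, 1 and 2 at an unadjusted p under 0.05), where the lowest adjusted p were 0.382, 0.447 and 0.0916.

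The counts of changed features moved with single libraries. In subgroup A edgeR called 47, 34 and 36 features without hDICER A library 1, 2 or 3, 232 without fDICER A library 1 and 32 without fDICER A library 2. In T it called 28, 30 and 27 without hDICER T library 1, 2 or 3, 352 without fDICER T library 1 and 37 without fDICER T library 2. In G it called 27, 4 and 2 without hDICER G library 1, 2 or 3, and 310, 57 and 78 without fDICER G library 1, 2 or 3. Scaling by library totals moved the median log2 difference of the named features by 0.33 in T and 0.16 in G. It called 83 higher and 31 lower in T, 58 and 48 in A, and 43 and 45 in G.

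In subgroup C no single feature passed. edgeR called 0 of 523 between the enzymes, with 101 at an unadjusted p under 0.05, 32 called by DESeq2 and 64 in 1 edgeR fit over 24 libraries. The median log2 difference of its 20-nt features was 0.63, and 14 of 64 were higher when adjusted over the list alone; the class passed with camera (adjusted p = 3.64e-13), with an adjusted p = 0.325 with an estimated correlation. 15-nt features had a median of -1.65 and were lower in 7 of 9 when adjusted over the list alone (camera adjusted p = 3.17e-07; adjusted p = 0.327 with an estimated correlation). For 22-nt features the median was -0.19 and camera gave an adjusted p = 0.287, and for 21-nt features -0.33 and 0.548. Features with A at nt 56 had a median of 0.46 and those of A and U alone 0.59 (camera adjusted p = 3.13e-07 and 3.19e-10; 13 and 6 higher when adjusted over the list alone). Features with G at nt 55, with G at nt 56, with 3 G or C and of 16 nt had medians of -0.73, -0.64, -0.97 and -0.9986 (camera adjusted p = 4.52e-08, 4.78e-06, 1.18e-06 and 7.01e-14). The 6 classes had adjusted p = 0.505, 0.617, 0.394, 0.313, 0.335 and 0.0997 with an estimated correlation. A and U at nt 54, A and U at nt 55, 1 G or C, 23 nt and 24 nt also passed upwards (camera adjusted p = 0.0280, 0.0406, 0.00204, 0.00385, 0.0217, 0.0447 and 0.00385; adjusted p = 0.633, 0.617, 0.617, 0.617, 0.617, 0.827 and 0.685 with an estimated correlation), with 1, 0, 0, 5, 0, 0 and 0 features changed when adjusted over the list alone. Triplets with 2 G or C passed downwards (camera adjusted p = 0.000310; adjusted p = 0.0997 with an estimated correlation). G at nt 54 in subgroup C is the Watson-Crick class, and mismatches are all the other features, so these are not separate results. Watson-Crick pairs of nt 1 and nt 54 had a median of -0.41 (camera adjusted p = 0.00385; adjusted p = 0.617 with an estimated correlation), and mismatches passed upwards with a median of -0.02, opposite in sign to the test (camera adjusted p = 0.00385; adjusted p = 0.569 with an estimated correlation). Camera called 19 of 28 classes in C, 0 of them with an estimated correlation (4 at an unadjusted p under 0.05, lowest adjusted p = 0.0997). Without fDICER C library 1, edgeR called 168 features, and without fDICER C library 2 it called 16.

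The third question is which products differ between the subgroups. For hDICER, 479 of 602 features differed between subgroups, among them 64 of 64 21-nt, 62 of 64 22-nt and 58 of 64 20-nt features. Of the changed 21-nt features 45 were highest in subgroup G and 46 lowest in T, and of the changed 22-nt features 28 were highest in T and 41 lowest in G. 26 of the changed 20-nt features were highest in C. The 6 largest named differences were all of triplets with C at nt 54, higher in T than in G: CGU_22 by 19.8-fold (edgeR adjusted p = 3.53e-15), CUC_22 by 16.9-fold, CCU_23 by 16.2-fold, CCC_22 by 15.6-fold, CCU_22 by 13.9-fold and CAU_22 by 13.5-fold. These counts and folds were not corrected for the substrate pool, whose triplets differed between subgroups before cleavage. In control library 1, CGU had 9763 of 896322 56-nt counts with U at nt 1 and 270 of 88603 with G. Over all lengths, triplets with C at nt 54 held 21.95% of the hDICER product counts in subgroup T and 6.46% in G. The 6 folds therefore combine the amount of the triplet with the site used. How much of the differences comes from the pool was not tested. Leaving out any 1 library gave 461 to 486 changed features.

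For fDICER, 84 of 622 features differed between subgroups, among them 20 of 64 21-nt, 15 of 64 20-nt and 10 of 64 22-nt features. Of the changed 22-nt features 9 were highest in T and 9 lowest in G, and of the changed 20-nt features 11 were highest in C and 12 lowest in G. CGG_20 was 36.4-fold higher in C than in G (adjusted p = 0.0240 in the edgeR test over all 4 subgroups), CGG_19 30.6-fold, CGU_20 17.6-fold and CAG_20 17.3-fold, while CUA_20 was 17.4-fold higher in A than in G and CCC_22 14.9-fold higher in T than in G. These pairs of highest and lowest subgroup were not tested themselves. These folds were not corrected for the substrate pool either. In control library 1, CGG had 678 of 267888 56-nt counts with C at nt 1 and 71 of 88603 with G. The count moved with single libraries. edgeR called 31 without fDICER A library 2, 40 without T library 2, 150 without G library 1, 11 without G library 2, 0 without G library 3 (152 at an unadjusted p under 0.05, DESeq2 not run there), and 167 without C library 1. Without the 4 libraries numbered 1 it called 309. DESeq2 called 178 over all libraries.

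The fourth question is how nt 1 and the triplet act together. RNAfold paired nt 1 with nt 54 in 64 of 64 substrates where these can form a Watson-Crick pair, in 24 of 32 with a G-U pair and in 0 of 160 with a mismatch, and paired nt 34, 35 and 36 in all 256. With hDICER the 22-nt share averaged over triplets ran from 18.8% ± 0.926 (SD, n = 3) for G at nt 1 with C at nt 54, and 19.2% ± 1.45 for G with U, to 71.1% ± 0.900 for A with G. A at nt 1 with C at nt 54, a mismatch, gave 23.96% ± 0.891, and A with U, a Watson-Crick pair, 40.8% ± 0.565. With hDICER, C at nt 54 had the lowest mean 22-nt share of the 4 bases in subgroups A, G and C; with fDICER it was lowest in A and C, and U was lowest in G (38.1% against 44.8%). C at nt 54 was below the mean of the bases in 12 of 12 hDICER libraries, by -12.3 points on average (exact sign-flip p = 0.000488, the smallest possible, adjusted p = 0.00146), and in 11 of 12 fDICER libraries, by -8.46 points (p = 0.000977, adjusted p = 0.00260). These p count each library singly and do not measure the spread between subgroups. G at nt 54 exceeded C by 47.2 ± 1.67 points in subgroup A, 30.0 ± 0.564 in G, 8.51 ± 1.24 in T and 3.46 ± 1.53 in C with hDICER (SD, n = 3 each; exact permutation p = 6.49e-05 between subgroups, the smallest possible). With fDICER the same contrast was 31.8 ± 6.12, 20.9 ± 5.33, 4.52 ± 2.69 and 6.51 ± 11.03 points (exact permutation p = 0.00435).

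**Figure D2:**
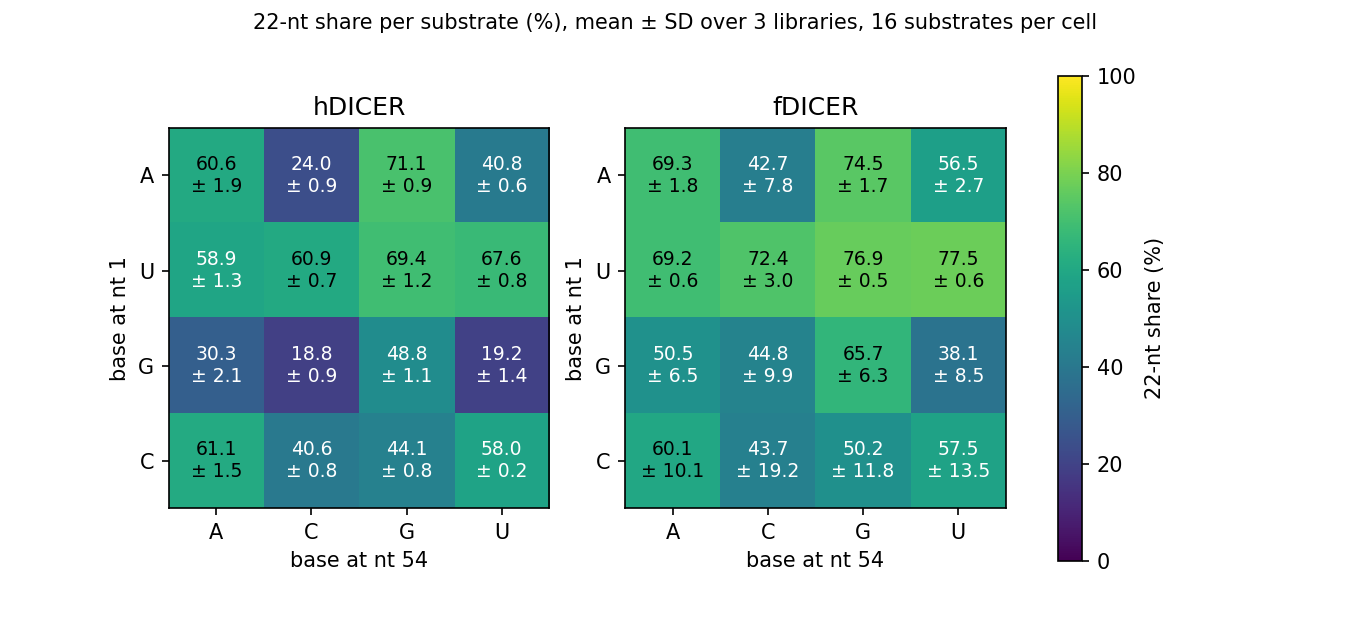
Mean 22-nt share (percent, over 16 triplets, n = 3 libraries) for each base at nt 1 and at nt 54, for hDICER and fDICER. With hDICER the share ran from 18.8% for G at nt 1 with C at nt 54 to 71.1% for A at nt 1 with G at nt 54.

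As pair classes, Watson-Crick substrates had a lower mean 22-nt share than mismatched ones in all 4 subgroups with hDICER, at 40.8% against 51.9% in A, 58.9% against 64.3% in T, 18.8% against 39.5% in G and 44.1% against 53.2% in C. The difference between these pair classes was not tested itself. Within a subgroup the Watson-Crick class is a single base at nt 54, so pairing cannot be told apart there from an effect of that base. The mismatch means also pool unlike bases. C at nt 54, a mismatch, lay below the Watson-Crick class in A (23.96%) and C (40.6%), and the other mismatched bases lay above it in each subgroup. G-U substrates did not follow 1 direction, with 69.4% in T and 19.2% in G. With fDICER the Watson-Crick and mismatch means were 56.5% and 62.2% in A, 69.2% and 74.9% in T, 44.8% and 58.1% in G and 50.2% and 53.8% in C, and G-U means were 76.9% in T and 38.1% in G. hDICER was below fDICER in the 22-nt share for each base at nt 54 in subgroups A, T and G, with all libraries separate (10% by chance) and differences from -3.37 points for A with G to -26.0 points for G with C; in subgroup C the libraries overlapped for each base. U at nt 56 exceeded the mean of the bases in the 22-nt share by 4.27 ± 1.70 points with hDICER and 5.06 ± 2.34 with fDICER, and C at nt 56 differed by -3.80 ± 1.91 and -6.39 ± 2.35 points (SD, n = 12), each in 12 of 12 libraries (exact sign-flip p = 0.000488, adjusted p = 0.00146). G at nt 55 differed by -3.68 ± 1.39 points in 12 of 12 hDICER libraries (exact sign-flip adjusted p = 0.00146), and by -0.51 ± 2.03 points in fDICER libraries, 7 of 12 below the mean (exact sign-flip adjusted p = 0.438). The sign flips at nt 55 and nt 56 also count each library singly. Single triplets of hDICER, chosen after their values were seen as the extremes, ran from 8.22% ± 0.698 for CCG in subgroup G to 77.6% ± 1.28 for GUU in subgroup A (SD, n = 3).

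The last question is which substrates are over-represented among products relative to the uncleaved pool. With hDICER 6 or 7 of the 8 triplets of 3 G or C were higher in each subgroup, and with fDICER 5, 8, 1 and 1 of 8 in A, T, G and C. All 8 triplets of A and U alone were lower in each subgroup with hDICER, and 8, 8, 4 and 7 with fDICER. Such counts do not compare the strength of the changes between the enzymes, since the fDICER comparisons had the larger dispersion. No class passed camera with an estimated correlation (lowest adjusted p = 0.153). GGG in subgroup C was 5.93-fold higher in hDICER products (log2 2.57 ± 0.51 SE, edgeR adjusted p = 0.00735) and 12.8-fold higher in fDICER products (log2 3.68 ± 0.73 SE, adjusted p = 0.0313), relative to the other triplets of the subgroup. UUA was 1.86-fold to 3.23-fold lower with hDICER and 7.54-fold to 10.8-fold lower with fDICER over the 4 subgroups. Without fDICER T library 1 it was 15.7-fold lower in T with fDICER, against 9.80-fold over all libraries. CGG was higher in all 4 subgroups with hDICER, by 2.69-fold in A, 2.15-fold in T, 2.24-fold in G and 1.96-fold in C, and AGG by 1.85-fold in A, 2.24-fold in T and 2.75-fold in G. UUU was lower with hDICER by 2.21-fold in A, 2.12-fold in T and 3.53-fold in G, UAU by 2.00-fold in A and 3.50-fold in G, and UCA by 2.59-fold in T and 2.00-fold in C. With fDICER, GGG was 5.68-fold higher in A and 5.79-fold in T, GGC 3.88-fold and 3.91-fold, and GGA was 3.99-fold and CUG 3.33-fold higher in G. GUA was 4.06-fold lower in A and 3.69-fold in T, AUA 2.57-fold in A and 4.86-fold in C, and CUA 3.78-fold in C.

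By base, G at nt 55 exceeded the other bases by 0.76 ± 0.10 log2 units with hDICER and 1.36 ± 0.51 with fDICER, and G at nt 56 by 0.59 ± 0.07 and 1.21 ± 0.43 (SD, n = 12), each in 12 of 12 libraries. U was below the other bases in 12 of 12 libraries of each enzyme at nt 54 (-0.52 and -0.70), at nt 55 (-0.49 and -0.94) and at nt 56 (-0.50 and -0.40), and so was A at nt 56 (-0.35 and -1.08). Each of these had an exact sign-flip p = 0.000488, the smallest possible, and adjusted p = 0.000781 over 24 tests. The flips count the 12 libraries singly, although 3 come from each subgroup. G at nt 54 exceeded the other bases by 0.36 ± 0.31 with hDICER, in 10 of 12 libraries (exact sign-flip adjusted p = 0.00370), and by 0.54 ± 0.50 with fDICER, in 11 of 12 (adjusted p = 0.00326). The triplets of A and U alone were lower in 8 of 8 in each subgroup with hDICER (8 of 8 each when adjusted over the list alone), and in 8, 8, 4 and 7 of 8 in A, T, G and C with fDICER (8 of 8 each when adjusted over the list alone). Camera adjusted p for this class were 3.32e-05, 0.000110, 1.93e-05 and 2.75e-05 with hDICER and 0.000255, 0.000583, 3.06e-05 and 7.88e-05 with fDICER. With an estimated correlation adjusted p = 0.340, 0.153, 0.384 and 0.307, and 0.449, 0.394, 0.371 and 0.260. Triplets of 3 G or C were higher in 6, 7, 6 and 7 of 8 with hDICER and in 5, 8, 1 and 1 of 8 with fDICER (6, 7, 6 and 7, and 6, 8, 3 and 1, when adjusted over the list alone). Camera adjusted p were 0.0145, 0.00330, 0.0144 and 0.00557, and 0.00732, 0.00140, 0.0141 and 0.00174, with adjusted p = 0.340, 0.286, 0.384 and 0.330, and 0.449, 0.405, 0.419 and 0.260, with an estimated correlation. Triplets with 2 G or C passed upwards in each subgroup (camera adjusted p = 0.00391, 0.00918, 0.00852 and 0.00485 with hDICER and 0.000441, 0.00140, 0.00494 and 0.00132 with fDICER), with adjusted p = 0.200, 0.252, 0.384 and 0.307, and 0.449, 0.394, 0.371 and 0.260, with an estimated correlation. Triplets with 1 passed downwards in A and T with hDICER and in A, T and C with fDICER (camera adjusted p = 0.0479, 0.0410, 0.00722, 0.00285 and 0.0115; adjusted p = 0.340, 0.262, 0.449, 0.394 and 0.260 with an estimated correlation). Substrates with G at nt 55 were higher in 13, 13, 11 and 10 of 16 with hDICER and 7, 11, 3 and 3 of 16 with fDICER (13, 13, 11 and 10, and 9, 11, 7 and 2, when adjusted over the list alone). Camera adjusted p were 0.000138, 5.21e-05, 0.000500 and 0.000372, and 0.000432, 0.000583, 0.000926 and 0.000403, with adjusted p = 0.200, 0.153, 0.384 and 0.307, and 0.449, 0.394, 0.371 and 0.260, with an estimated correlation. G-U pairs of nt 1 and nt 54, which in subgroup G are the triplets with U at nt 54, were lower there with hDICER (10 of 16 lower and 1 higher, the same when adjusted over the list alone; camera adjusted p = 3.91e-05, and adjusted p = 0.384 with an estimated correlation). They did not pass in T with either enzyme or in G with fDICER (camera adjusted p = 0.146, 0.390 and 0.0569). Watson-Crick pairs of nt 1 and nt 54 were higher in subgroup C with hDICER (9 of 16 higher and 1 lower, the same when adjusted over the list alone, camera adjusted p = 0.00314, and adjusted p = 0.486 with an estimated correlation) and lower in subgroup A (3 higher and 8 lower, the same when adjusted over the list alone, camera adjusted p = 0.0443, and adjusted p = 0.490 with an estimated correlation). With fDICER they passed upwards in C (camera adjusted p = 0.00108, and adjusted p = 0.260 with an estimated correlation; 3 higher, 3 when adjusted over the list alone). In subgroups A and C mismatches are all triplets outside the Watson-Crick class, so their opposite direction in these 3 comparisons is not a separate result. Their camera adjusted p were 0.0443 in hDICER A, 0.00314 in hDICER C and 0.00108 in fDICER C (adjusted p = 0.340, 0.307 and 0.260 with an estimated correlation). In subgroup G with hDICER mismatches passed upwards (camera adjusted p = 0.0203, and adjusted p = 0.558 with an estimated correlation).

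**Figure D3:**
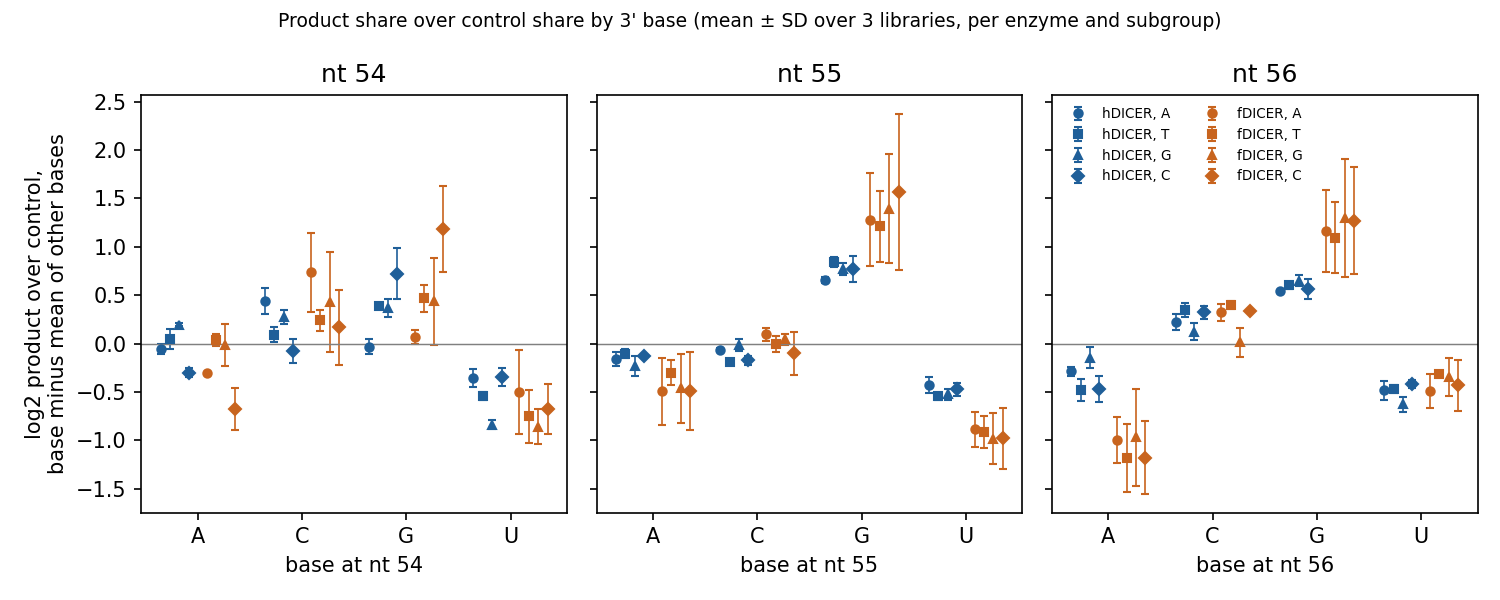
Log2 ratio of product share to control share of each base over the other bases at nt 54, 55 and 56. Points are means of 3 libraries for each enzyme and subgroup, and error bars are their SD. G at nt 55 lies above 0 in all 12 libraries of each enzyme, with means of 0.76 for hDICER and 1.36 for fDICER.

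Counts of changed substrates of 64 were 46, 53, 43 and 44 in subgroups A, T, G and C with hDICER and 32, 43, 10 and 16 with fDICER. The edgeR common dispersion was 0.00677, 0.00576, 0.00919 and 0.0123 with hDICER and 0.0588, 0.0371, 0.103 and 0.132 with fDICER. Lower counts with fDICER therefore do not show weaker changes. Camera called 12 of 18, 9 of 19, 10 of 19 and 10 of 18 classes with hDICER and 9, 8, 7 and 11 with fDICER, and 0 of them with an estimated correlation (3, 4, 1 and 1, and 0, 1, 0 and 1, at an unadjusted p under 0.05), where the lowest adjusted p was 0.153. These classes overlap, so their counts are not of separate results. The fDICER counts moved with single libraries. With 1 control library left out, the lone other one is assumed to vary like the product libraries. Without control library 1 edgeR called 0 in each of A, T, G and C (16, 33, 12 and 14 at an unadjusted p under 0.05), and without control library 2 also 0 (17, 30, 10 and 7); DESeq2 was not run with libraries left out. The log2 changes of the 24 named fDICER substrates had the same direction in 48 of 48 values without 1 of the control libraries, and moved by a median of 0.09 and at most 0.34. The naming rule had required every product library to lie on the same side of both control libraries. The kept direction was thus set by the choice of substrates and is no support for them. edgeR called 0 without fDICER A library 2 (24 unadjusted) in A, 6 without T library 2 in T, 42, 5 and 0 (18 unadjusted) without G library 1, 2 or 3 in G, and 33, 1 and 2 without C library 1, 2 or 3 in C. With hDICER it called 27 in G without G library 2 and 24 in C without control library 2. Scaling by library totals, which compares 1 subgroup with a control that holds all 4, moved the median log2 change of the named substrates by 2.02, 1.57, 4.93 and 3.09 with hDICER and 2.05, 1.59, 4.71 and 3.12 with fDICER, so the changes given are relative to the other triplets of the subgroup.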

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

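The tests that weigh explanations in this part, and the counts over other splits of the libraries, were chosen only after the results were seen. The tests of extra 5′ bases and of a bias by the 3′ bases took the place of earlier ones whose values had been seen, the latter repeatedly, and its bound of 2 times was set when the ratios could be read.

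The effect of a triplet base on the 22-nt share differed between substrate subgroups. With hDICER the exact permutation p of this difference was 6.49e-05 at nt 54, the smallest possible, 0.000195 at nt 55 and 0.00013 at nt 56 (adjusted p = 0.000195, 0.000292 and 0.00026 over 6 tests). With fDICER it was 6.49e-05 at nt 54 and 0.000714 at nt 55 (adjusted p = 0.000195 and 0.000857), and 0.21 at nt 56. The effect of a base on the ratio of product to control also differed between subgroups. With hDICER the exact permutation p was 6.49e-05 at nt 54, 0.0118 at nt 55 and 0.00526 at nt 56 (adjusted p = 0.00039, 0.0176 and 0.0158), and with fDICER 0.00942 at nt 54 (adjusted p = 0.0176), 0.882 at nt 55 and 0.832 at nt 56.

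Some sequences lay outside the comparisons. Control library 1 held 30.7% of its counts in 57-nt and 0.932% in 58-nt sequences. Fragments under 15 nt made up from 0.556% to 4.47% of the counts of an fDICER library, and these lengths are not present in the hDICER files. Fragments of 34 nt reached 42 counts in an fDICER library, with over 3 counts in 5 fDICER libraries and 0 counts in each hDICER library. Fragments of over 50 nt reached 6 counts in 1 fDICER library and at most 3 in an hDICER library.

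With hDICER the 22-nt share was 64.7% ± 0.942 in subgroup T and 32.2% ± 1.78 in subgroup G (SD, n = 3). A ligation or amplification bias for particular product molecules would act alike in all subgroups, because the products do not contain nt 1. In 64 of 64 triplets every subgroup T library lay above every subgroup G library in the ratio of 22-nt to 21-nt counts. The median difference was 2.62 log2 units. Chance gives such an order in 5% of cases for 1 triplet, and the triplets share the same libraries, so they are not independent tests. A difference between subgroups in every triplet argues against such a bias. Substrates with extra 5′ bases in subgroup G could move the site towards the end and give shorter 3′ products; in control library 1, 77.8% of the sequences with G next to the core had 57 nt (19.3% to 35.6% for the other bases), but control library 2 holds none and products lack the 5′ end, so this cannot be told apart from an effect of nt 1. A difference between the separate preparations of the subgroups cannot be told apart from the subgroup either, and an effect of nt 1 on the cleavage site stays open.

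In subgroups A, G and C the 22-nt share varied more between fDICER libraries than between hDICER libraries, where the largest range of a group was 3.43 points. In T it varied less with fDICER, over 0.531 points against 1.74 with hDICER. A batch shared by the fDICER libraries numbered 1 would leave libraries 2 and 3 close together, but in subgroups A and C these differed by 5.77 and 10.9 points, which argues against it as the whole cause there. In subgroup G libraries 2 and 3 differed by 1.62 points and library 1 lay 10.6 points from the nearest of them, so such a batch may account for the spread in G. No biological explanation was tested for differences between libraries of 1 group.

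With hDICER, G exceeded the other bases in the ratio of product to control by 0.36 ± 0.31 log2 units at nt 54, 0.76 ± 0.10 at nt 55 and 0.59 ± 0.07 at nt 56 (SD, n = 12). A preparation bias that depends on the 3 variable 3′ bases alone would give each base the same effect in all subgroups, but 4 of 12 base effects differed with each control library, over a range of more than 2 times that by which the 2 control libraries disagree. These were G at nt 54 (at least 3.38 times, exact permutation adjusted p = 0.0113 over the 12) and 1 of the 3 other bases at each position, A at nt 54 (2.07 times, 0.00701), C at nt 55 (2.08 times, 0.0113) and A at nt 56 (5.68 times, 0.0369), which argues against the bias as the whole cause of these 4 effects, narrowly for A at nt 54 and C at nt 55. For G at nt 55 and nt 56 it was at least 1.20 and 2.21 times (exact permutation adjusted p = 0.267 and 0.323), so the effect of G was not shown to differ there and for it the bias cannot be told apart from a preference of the enzyme. A bias that differs between the separate preparations, and a preference of the enzyme, possibly one that depends on nt 1, stay open at all 3 positions. So does a bias in the circular ligation of the control libraries that depends on nt 1 as well as the triplet. Both control libraries would share it, so their disagreement does not bound it.

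In the 10 splits of the 6 libraries of a subgroup, the real split of the enzymes gave 124, 98 and 118 changed features in A, T and G, with 0 as the highest other, so that 1 of 10 splits gave as many in each. 10 splits are too few for a share under 0.05. In C and for the interaction the real count was 0 (edgeR; 101 and 43 at an unadjusted p under 0.05, 32 and 21 by DESeq2). Every split then gives as many by construction, 10 of 10 and 100 of 100, with 0 and 47 as the highest other, and these counts decide nothing. For the hDICER subgroup difference 1 of 100 splits, the real one, gave 479 features, with 13 as the highest other, a share under 0.05. Each subgroup was prepared separately, so this shows that libraries of a subgroup resemble each other. It cannot exclude a difference between the preparations or in the substrate pool. For the fDICER subgroup difference 2 of 100 splits gave at least the real 84 features, and 1 other split gave 90, so the share is under 0.05 although another arrangement called more.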

How the results depend on the processing

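Chosen only after seeing the data were all product lengths, 20 to 22 nt only, leaving out the fDICER libraries numbered 1 or the shallowest fDICER library, a control with 57-nt and 58-nt sequences, and subgroup labels permuted within library numbers. Leaving single libraries aside, 105 of 111 values of site shares and 189 of 192 base ratios were unchanged in direction and call or moved by less than their spread, as were 95 of 126 counts of changed features within 1.5 times and 11 of 24 class counts. Of 668 values of named features 614 kept their direction and call, 36 kept the direction alone and 18 reversed. With single libraries left out, 424 of 432 site shares, 68 of 112 counts and 283 of 420 named features held, and 137 named features kept the direction alone. The labels link no equal replicate numbers, and not every pair of same-numbered libraries had a correlation over 0.1. Profiles of the 2 enzymes with the same number had a median correlation of -0.0195 against 0.0273 for other numbers (3 of 12 pairs over 0.1). Within an enzyme equal numbers were more alike, a hint from the data at a shared batch: subgroups had 0.146 against -0.101 with hDICER (12 of 18 pairs over 0.1) and 0.453 against -0.354 with fDICER (16 of 18), and 8 of 12 hDICER and 7 of 12 fDICER libraries correlated best with their own number. With the number as a block (labels permuted within numbers, 13824 arrangements, smallest p 0.00174), the fDICER differences between subgroups of 3.21, 21.96 and 23.03 points at 20, 21 and 22 nt passed, each with an adjusted exact permutation p = 0.0430, in a range over all alternatives from 0.0236 to 0.250, 0.0345 to 0.292 and 0.0236 to 0.292. With the replicate number as a block, changed features numbered 72 in subgroup A between the enzymes, 238 in the fDICER subgroup difference, and 15 in hDICER C, 17 in fDICER G and 0 in fDICER A and T for product against control (edgeR; 30 and 32 at an unadjusted p under 0.05; DESeq2 not run with a block). With all product lengths the enzyme comparison called 266 in A, 220 in G and 21 in C, and fDICER C against control 7; with 20 to 22 nt only it called 75 in G and 1 in C. The lengths under 15 nt are only in the fDICER files, so the first setting adds features found in 1 enzyme by construction. Without a count filter C had 1 and the fDICER subgroup difference 159; with library totals C had 8, and in 1 fit over 24 libraries 64. With at least 100 counts the interaction called 4, the hDICER subgroup difference 303 and fDICER G against control 0 (edgeR; 27 at an unadjusted p under 0.05; 31 by DESeq2 at the usual filter). DESeq2 called 32 in C, 21 for the interaction, 178 for the fDICER subgroup difference, and 31 and 27 for fDICER G and C against control. Without the fDICER libraries numbered 1 the interaction called 122 and the fDICER subgroup difference 309. With the control limited to the subgroup, fDICER G and C gave 17 and 9. Camera with an estimated correlation called 0 classes in each of 12 comparisons (0 to 4 at an unadjusted p under 0.05), and with the preset one 10 in subgroup T with features of at least 100 counts on average. The cause was not tested for these changes. With library totals, fDICER A, G and C against control called 60, 64 and 61, and 18 named substrates reversed, by construction, since the control total covers all 4 subgroups. The log2 changes were then 1.02 for UAU, 1.11 for UUA and 0.87 for UUU in hDICER A, 0.17 for UCA and 0.49 for UUU in T, 3.11 for UAU, 3.33 for UUA and 3.11 for UUU in G, and 2.17 for CUA, 2.09 for UCA and 1.55 for UUA in C. With fDICER they were 0.68 for AUA and 0.0463 for GUA in A, 4.06 for AUU, 1.65 for UUA and 3.53 for UUU in G, and 0.86 for AUA and 1.17 for CUA in C. As a mean over variants with at least 20 or 50 counts, the 22-nt share, hDICER minus fDICER, subgroup C, was -1.93 points, and with at least 200 counts -1.94; the cause was not tested. With single libraries left out, counts between the enzymes ran from 32 (without fDICER A library 2) to 232 (fDICER A library 1) in A, 27 (hDICER T library 3) to 352 (fDICER T library 1) in T, 2 (hDICER G library 3) to 310 (fDICER G library 1) in G and 0 to 168 (fDICER C library 1) in C, the interaction from 0 to 9 (fDICER T library 1) and the fDICER subgroup difference from 0 (fDICER G library 3) to 167 (fDICER C library 1). Against control they ran from 27 to 43 in hDICER G, 24 to 49 in hDICER C, and 0 to 45, 0 to 51, 0 to 42 and 0 to 33 in fDICER A, T, G and C, with 0 without either control library, where the lone other one is assumed to vary like the product libraries, and the highest without library 1 of the subgroup. Where edgeR called 0 with a library left out, 39 to 99 features in C, 31 to 71 for the interaction, 152 for the fDICER subgroup difference and 7 to 33 against control had an unadjusted p under 0.05, and DESeq2 was not run. The 21-nt share, hDICER minus fDICER over the subgroups, ran from 3.83 (without fDICER C library 1) to 6.70 points (fDICER C library 3), in C from -10.3 to 1.22 and the 22-nt share in C from 7.58 to -6.14, for the same libraries left out. The fDICER ranges between subgroups ran from 2.42 to 4.42 points at 20 nt, 19.8 to 26.1 at 21 nt and 20.7 to 27.1 at 22 nt. With 57-nt and 58-nt control sequences 3 base ratios moved by more than their spread, and the cause was not tested. At the depth and spread of the libraries, simulated recovery of a 2-fold change was 4.08% for the fDICER subgroup difference, 14.1% for the interaction, 23.2% between the enzymes in C and 30% for fDICER C against control, so changes of this size can be missed there.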

Other observations

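The tests of nt 1 with nt 54 and of the likeness of the enzymes were chosen only after the values were seen. The test of the ratio of product to control against the 22-nt share was stated before its values were seen.

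The base next to the core differed between the 2 lengths of control sequences. In control library 1, G made up 4.84% of the bases at that place in 56-nt sequences and 37.7% in 57-nt sequences, and the base added at the 5′ end was U in 62.2% and G in 24.5% of the latter.

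A hypothesis is that a base pair between nt 1 and nt 54 may lower the 22-nt share. After the mean of each base was taken out, the 4 Watson-Crick combinations had a mean of -7.75 points with hDICER, and 2 of the 24 ways to match 4 bases to 4 bases were as low. With fDICER the mean was -4.19 points, and 3 of 24 ways were as low. The lowest mean, -11.9 and -9.30 points, came from matching A with C, U with A, G with U and C with G, and the pair of G with C had 1.84 and 3.45 points. The rule chosen for the hypothesis was that the Watson-Crick matching be the lowest of the 24. It was not the lowest with either enzyme, so this test did not bear the hypothesis out. A part played by pairing is not excluded, since the Watson-Crick means were negative.

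A second hypothesis is that the enzymes may share their dependence on nt 1 and nt 54. Over the 16 combinations the mean 22-nt shares of hDICER and fDICER had Pearson's r = 0.914 and Spearman's rho = 0.918 (permutation p = 1e-05 each, the smallest possible), and r = 0.889 without the 2 combinations farthest from the median. The 16 combinations are not independent samples, since 4 share each subgroup's libraries.

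The remaining hypothesis, that triplets cleaved more often at the 22-nt site could give more product, was not borne out. Across triplets, which are not independent replicates, the correlation of the ratio of product to control with the 22-nt share was positive in 3 of 12 libraries of hDICER and 3 of 12 of fDICER, all of subgroup G (0.0579 to 0.215 and 0.106 to 0.202). The median correlations were -0.337 and -0.224.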
